A study of Mus musculus with 21 samples.

How the data were processed

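RNA from the heart apex of 7-day-old ICR mice, resected at day 1, was sequenced on a BGISEQ-500 in 7 groups of 3 libraries. The labels describe library selection as oligo dT or rRNA depletion without saying which. The authors deposited 1 table of FPKM values (fragments per length of transcript and mapped total, 2 decimals) for 18762 genes, and their notes name HISAT, Bowtie2 2.2.5 and the mouse build mm9. The counter, annotation release and filters are not stated. Every value column was mapped to a library of the labels, and 0 columns were left over. Of the genes, 864 start with a predicted transcript, and the symbol Plin2 stands on 2 entries, of which 1 passed the filter.

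Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, 12433 in all. A linear model with 1 mean per group was fitted to all 21 libraries with limma 3.58.1 in R 4.3.3, leaving 14 residual degrees of freedom, with empirical Bayes moderation and a mean-variance trend. The p values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. Each of the 6 drugs was compared with the control, metoprolol with propranolol, and isoproterenol with each of these. An F test covered the 7 groups. Libraries of the same number in their titles were checked for pairing. Their residual correlations ran from -0.54 to 0.29 (median -0.03), so no pairing was modelled.

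Gene lists, 39 in all, were written from general knowledge, and the 34 with at least 5 tested members were tested with camera from limma at its preset inter-gene correlation of 0.01. An estimated correlation and fry were run as alternatives. The lists cover proliferation (mitosis, DNA replication), cardiac growth and muscle programmes, channels, metabolism, hormone and stress responses, and markers of cell types. For 7 lists, mitosis and adult sarcomere among them, the mean of members per library was compared with a two-sided exact permutation test, whose smallest p is 0.10.

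Gene names follow a rule. For each drug against control these were the 10 largest called changes each way with all 3 drug libraries outside the 3 controls, at least 1 FPKM in a group and a symbol that is no bare locus name. If fewer than 5 passed, the 10 of smallest p were taken. Added were the 4 members of smallest p of each called list, 2 members of the mitosis, adult sarcomere, extracellular matrix and β-adrenergic lists, and drug targets, among them Adrb1, Hcn4, Kcnh2 and Cacna1c. Between drugs it was 5 each way, and for the F test the 10 of smallest p. The text gives a part of these as examples, and some named genes are not reported here. The comparisons, lists, naming rule and first set of alternatives were fixed before the data were examined.

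Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios rescaling, a fit of the compared groups alone, no variance trend, robust moderation, the title number as a block, and leaving out each library in turn. Chosen after the data were examined were a covariate of 4 Y-linked genes, a correction of each library for transcript length and GC content by splines with 4 degrees of freedom, leaving out 4 libraries (those with the highest Mylpf, Myl7, Sftpc or Alb, markers of skeletal muscle, atrium, lung and liver), each drug against the other 5, and the F test of the 5 anti-arrhythmic groups. Length and GC came from another build and annotation than mm9, so no coordinates were used. Of the deposited genes 96.7% were matched (17783 by RefSeq transcript and 366 by Entrez identifier only).

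Without counts or read totals, only relative depth per library is known. In simulated data with 50 genes changed at each size, false calls were 5 among 12233 genes. Recovery was 22%, 70%, 98% and 100% at changes of 0.25, 0.5, 1 and 2 log2. An unchanged group gave 0 calls. Lowering mitosis by 0.3 log2 called that list alone, but shuffled isoproterenol and control libraries called up to 22 lists.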

Results

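RNA was sequenced from the apex of hearts of ICR mice that had undergone apical resection, removal of the tip of the ventricle, as 1-day-old neonates. The animals then received subcutaneous injections, given in the labels as a course of 7 consecutive days, and were sampled at postnatal day 7. There were 7 groups of 3 libraries, 21 in all. The control group is labelled apical resection alone, and its injection, if any, is not stated. The drug groups received isoproterenol, an agonist of β-adrenergic receptors, or 1 of 5 anti-arrhythmic drugs. These were amiodarone, which blocks potassium and other channels, the β-blockers metoprolol and propranolol, the sodium channel blocker lidocaine, and ivabradine, which blocks the pacemaker current. Doses are not in the labels, and the labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between libraries. Each comparison asks which transcripts of the healing neonatal heart differed with a drug.

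The deposited values were FPKM for 18762 genes, with no read counts, so the absolute depth is unknown and no counting interval can be given. The sum of FPKM per library ran from 496304 to 552905, and 16348 to 16746 genes were above 0. Lattices in the values of 130 low genes gave relative depths of 0.948 to 1.04 between libraries. Libraries of a group correlated across genes at r of 0.988 to 0.996. The first principal component (27.5% of the variance) ran from -30.3 to -16.2 in the controls and from -3.45 to 15.1 in the 18 drug libraries. The second (16.0%) ran from 14.3 to 21.2 in the isoproterenol libraries and from -10.7 to 8.06 in the others.

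**Figure D1:**
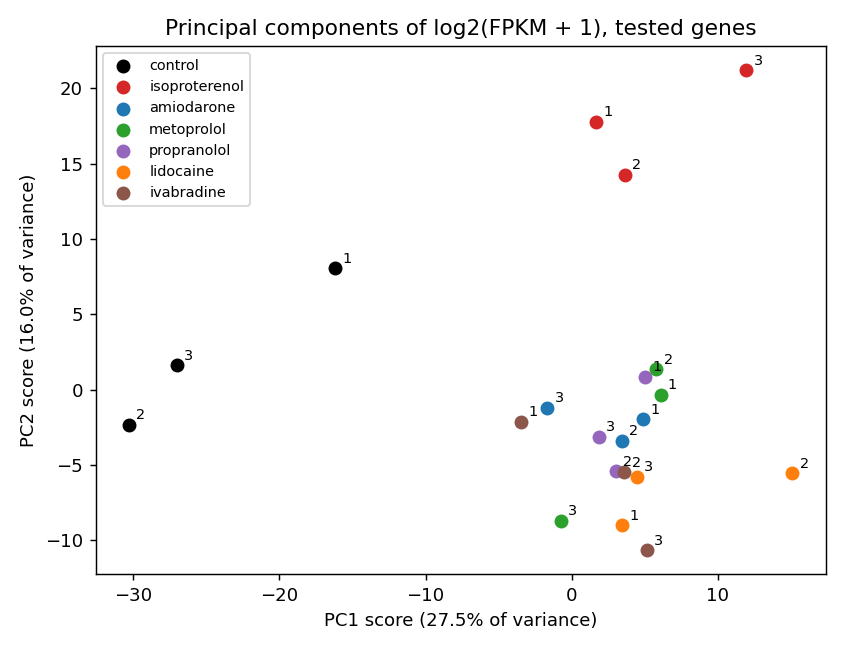
Scores of the 21 libraries on the first and second principal components of log2(FPKM + 1), 1 point per library, coloured by group. The controls lie from -30.3 to -16.2 on the first axis, and the isoproterenol libraries from 14.3 to 21.2 on the second.

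Some libraries carried transcripts of other tissues. Sftpc, a lung surfactant gene, stood at 222 FPKM in amiodarone 2 and 9.10 FPKM in lidocaine 1, and Alb, made in liver, at 10.8 FPKM in propranolol 1. The atrial gene Myl7 stood at 176 FPKM in isoproterenol 3, and at no more than 3.26 FPKM elsewhere. The fast skeletal muscle gene Mylpf stood at 62.7 FPKM in control 3, against 8.65 and 14.7 FPKM in the other controls, and at 30.4 FPKM in amiodarone 3. Lyz2, a myeloid gene, ran from 91.8 to 405 FPKM within the controls. Transcripts of the Y-linked genes were present in 2 control, 0 isoproterenol, 3 amiodarone, 1 metoprolol, 3 propranolol, 1 lidocaine and 2 ivabradine libraries, and the labels give no sex.

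**Figure D2:**
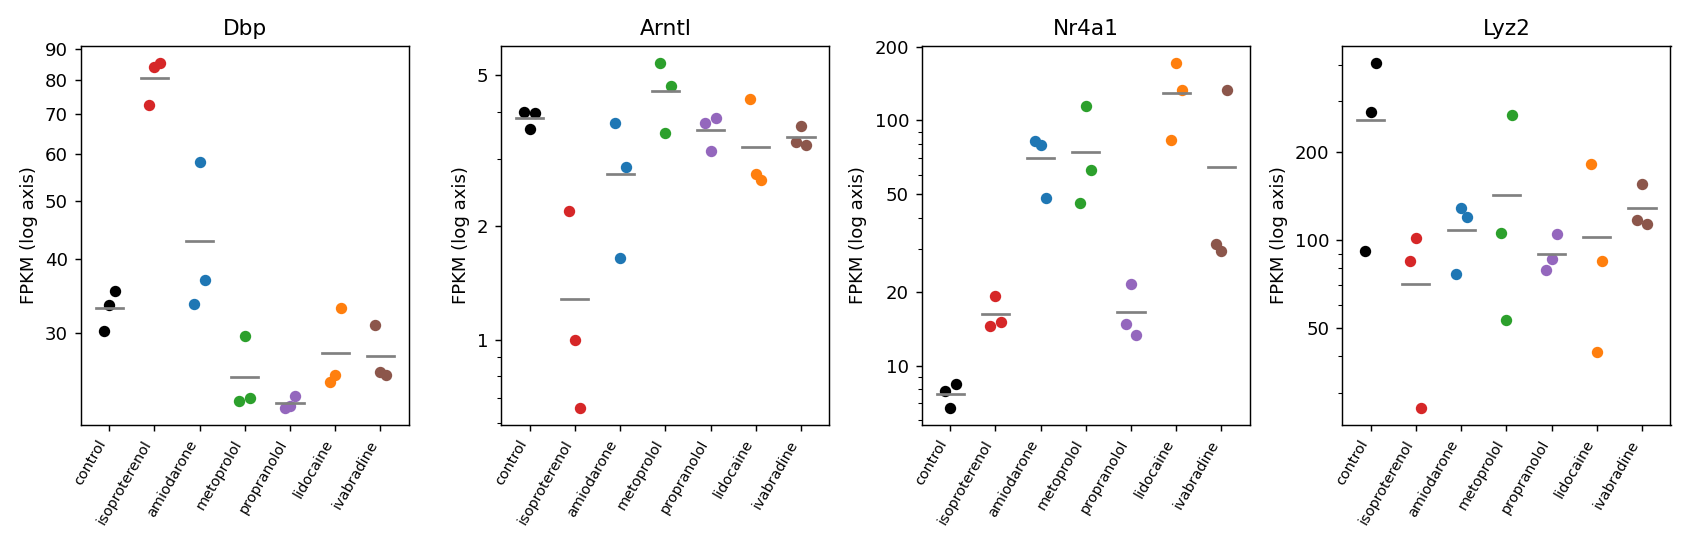
FPKM of Dbp, Arntl, Nr4a1 and Lyz2 in each of the 21 libraries on a log axis, 1 point per library, with group means as bars. Dbp lay between 72.5 and 85.3 FPKM with isoproterenol and between 30.3 and 35.3 FPKM in the controls.

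Across all 7 groups, 4962 of 12433 tested genes (39.9%) differed in limma's F test (Benjamini-Hochberg adjusted), and among the 5 anti-arrhythmic groups 132 genes (1.06%) did. The smallest p values among the 7 groups included Rgs2, a brake on G protein signalling, at 11.2 FPKM in controls, 13.3 FPKM with isoproterenol and 16.4 to 29.1 FPKM with the anti-arrhythmic drugs (adjusted p = 2.2e-06). Cxcr4, a chemokine receptor, stood at 15.9 FPKM in controls, 8.90 FPKM with isoproterenol and 3.95 to 6.41 FPKM with the others. Stbd1, a glycogen-binding protein, stood at 8.37, 8.17 and 14.1 to 21.9 FPKM, and Nes, an intermediate filament gene, at 24.5, 21.5 and 28.4 to 39.4 FPKM, in the same order. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 47.5 FPKM in controls, 18.2 FPKM with isoproterenol and 37.8 to 43.0 FPKM with the others (adjusted p = 2.4e-06). The remaining genes of the 10 smallest p values were Lime1, Ggta1, Slc7a1, Tmem100 and Maff. The count among the 5 anti-arrhythmic groups fell to 70 to 84 without amiodarone 1 or 2, propranolol 1 or 3, or lidocaine 1 or 2. It was 76 with no filter and 11 without the 4 libraries named below.

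In the accounts of single drugs below FPKM values are mean ± SD of 3 libraries, log2 values are fold changes ± SE, medians of a list are log2 fold changes, counts over the list alone are adjusted over its members only, and adjusted p values are from limma for genes and camera for lists. Refits are fits without 1 library, rescaled, with a Y-linked covariate, corrected for length and GC, without the 4 libraries with the highest value of an other-tissue marker above (Mylpf in control 3, Myl7 in isoproterenol 3, Sftpc in amiodarone 2 and Alb in propranolol 1, with lidocaine 1 and amiodarone 3 kept), or with other variance and filter settings. Gene names given as largest changes had all 3 drug libraries on the same side of all 3 controls.

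With isoproterenol, the clock and fatty acid oxidation lists were higher, the 2 of 13 list calls that held with an estimated correlation. The mitosis and DNA replication lists were lower and the ion channel list higher, calls that did not hold so (adjusted p = 0.19, 0.19 and 0.055). Ube2c (Entrez 68612), which drives mitotic exit, fell from the control level (23.3 ± 4.24 against 63.5 ± 8.68 FPKM, log2 -1.42 ± 0.14, adjusted p = 5.8e-06), as did the cyclin Ccnb1 (Entrez 268697; 5.26 ± 0.675 against 13.7 ± 0.646 FPKM, log2 -1.24 ± 0.12, adjusted p = 5.8e-06). Cdkn1a (Entrez 12575) also fell (18.2 ± 2.60 against 47.5 ± 3.45 FPKM, log2 -1.34 ± 0.10, adjusted p = 8.7e-07). Dbp (Entrez 13170), a transcription factor of the clock's output arm, rose (80.6 ± 7.00 against 33.0 ± 2.55 FPKM, log2 1.26 ± 0.15, adjusted p = 2.9e-05), and so did Slc9a3, a sodium-proton exchanger (log2 1.21 ± 0.12, adjusted p = 5.8e-06). Acta1, the skeletal isoform of α-actin that neonatal heart also expresses, rose (348 ± 180 against 121 ± 72.9 FPKM, log2 1.62 ± 0.42, adjusted p = 0.0070, lost in a fit of the 2 groups alone or without isoproterenol 3, adjusted p = 0.052 to 0.055). Large falls included B2m, the light chain of MHC class I (108 ± 19.5 against 548 ± 252 FPKM, log2 -2.26 ± 0.50, adjusted p = 0.0024), and the fast skeletal muscle gene Tnnc2 (log2 -3.04 ± 0.78, adjusted p = 0.0066), which was highest in control 3 (39.5 FPKM). In all, 1042 genes were higher and 3212 lower (34.2% of those tested; 24.5% of calls higher, or 56.0% higher, 2027 against 1593, with rescaling), and 8 higher and 144 lower genes changed by at least 1 log2. Unscaled, the 3 drug libraries did not overlap the controls in 5567 of 12433 genes. For each drug chance gives 10%, and a scale offset can give more.

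Mitosis genes under isoproterenol were lower as a group: 0 rose and 32 fell of 33 (0 and 33 over the list alone), median -0.87. For the mitosis list, adjusted p = 8.3e-19, and adjusted p = 0.19 with an estimated correlation. Further examples were Cks2 and Cdk1 (-1.20 ± 0.12 for Cks2 and -1.07 ± 0.12 for Cdk1, adjusted p at most 1.9e-05). Among DNA replication genes 0 rose and 28 fell of 30 (0 and 28 over the list alone), median -0.60, including the ribonucleotide reductase subunit Rrm2 and the sliding clamp Pcna (-1.33 ± 0.14 for Rrm2 and -0.76 ± 0.08 for Pcna, adjusted p at most 1.7e-05). Camera gave the DNA replication list adjusted p = 2.2e-12, and adjusted p = 0.19 with an estimated correlation. Averaged per library, the 33 mitosis genes stood at 2.59 ± 0.25 log2(FPKM + 1) with isoproterenol and 3.50 ± 0.07 in controls, with no overlap of the groups (exact permutation test, two-sided, p = 0.10, the smallest p that 3 against 3 allows). Of p53 targets, 1 rose and 10 fell of 16 (1 and 11 over the list alone), median -0.30. For p53 targets, adjusted p = 0.011, and adjusted p = 0.31 with an estimated correlation. Those that fell included the apoptosis gene Bax (log2 -0.57 ± 0.08, adjusted p = 8.5e-05), while Sesn1 rose (log2 0.40 ± 0.08, adjusted p = 8.9e-04).

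Fatty acid oxidation genes under isoproterenol, of which 19 rose and 1 fell of 28 (19 and 1 over the list alone), median 0.31, included both subunits of the trifunctional protein, Hadha and Hadhb, and the dehydrogenase Acadm (0.44 ± 0.05 for Hadha, 0.49 ± 0.05 for Hadhb and 0.49 ± 0.05 for Acadm, adjusted p at most 2.5e-05). Camera gave the fatty acid oxidation list adjusted p = 1.5e-15, and adjusted p = 0.049 with an estimated correlation. Of oxidative phosphorylation genes 11 rose and 0 fell of 37 (11 and 0 over the list alone), median 0.06, -0.01 without the 4 libraries. The oxidative phosphorylation list was given adjusted p = 2.0e-05, and adjusted p = 0.57 with an estimated correlation. Of cardiac ion channels 13 rose and 0 fell of 25 (16 and 0 over the list alone), median 0.34, among them the potassium channel Kcnh2 and the pacemaker channel Hcn4 (0.42 ± 0.08 for Kcnh2 and 0.93 ± 0.18 for Hcn4, adjusted p at most 0.0012). With isoproterenol cardiac ion channels had adjusted p = 1.1e-09, and adjusted p = 0.055 with an estimated correlation. The adult sarcomere list held 0.74 ± 0.10 for Cmya5, 0.34 ± 0.05 for Ldb3 and 0.38 ± 0.07 for Myh6 (adjusted p at most 8.3e-04), and in it 11 rose and 1 fell of 22 (12 and 3 over the list alone), median 0.22. The adult sarcomere list had adjusted p = 5.1e-06, and adjusted p = 0.19 with an estimated correlation. Of the β-adrenergic pathway 8 rose and 4 fell of 21 (11 and 4 over the list alone), median 0.19, with the adenylyl cyclase Adcy5 higher and the arrestin Arrb2 lower (0.80 ± 0.09 for Adcy5 and -0.71 ± 0.10 for Arrb2, adjusted p at most 1.0e-04). For the β-adrenergic pathway list, adjusted p = 4.0e-04, and adjusted p = 0.12 with an estimated correlation. The receptor Adrb1 changed by 0.27 ± 0.09 and the calcium channel Cacna1c by 0.30 ± 0.10 (adjusted p at most 0.029). These calls did not hold throughout (Adrb1 lost in several refits, adjusted p = 0.062 to 0.18; Cacna1c lost in several refits, adjusted p = 0.057 to 0.15).

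Clock genes were higher with isoproterenol as a group (10 rose and 2 fell of 17 (11 and 2 over the list alone), median 0.45), with 0.74 ± 0.09 for Tef, 0.87 ± 0.11 for Per3 and 0.63 ± 0.12 for Nr1d2 (adjusted p at most 6.7e-04). Camera gave the circadian clock list adjusted p = 4.5e-07, and adjusted p = 0.049 with an estimated correlation. Of macrophage markers 0 rose and 15 fell of 18 (0 and 16 over the list alone), median -1.26, such as the receptors Cx3cr1 and Csf1r (-0.96 ± 0.10 for Cx3cr1 and -1.06 ± 0.13 for Csf1r, adjusted p at most 3.2e-05). Macrophage markers were given adjusted p = 1.4e-06, and adjusted p = 0.41 with an estimated correlation. Of neutrophil markers 0 rose and 6 fell of 10 (0 and 9 over the list alone), median -1.06, such as S100a9 (log2 -2.07 ± 0.48, adjusted p = 0.0034, lost in a fit of the 2 groups alone, adjusted p = 0.064). With isoproterenol neutrophil markers had adjusted p = 0.010, and adjusted p = 0.57 with an estimated correlation. Of interferon response genes 0 rose and 15 fell of 18 (0 and 17 over the list alone), median -0.61, for example the antiviral gene Oas2 (log2 -0.83 ± 0.12, adjusted p = 1.2e-04). The interferon response list had adjusted p = 9.1e-05, and adjusted p = 0.56 with an estimated correlation. Extracellular matrix genes did not pass as a list (0 rose and 8 fell of 30 (0 and 6 over the list alone), median -0.35). For the extracellular matrix list, adjusted p = 0.10, and adjusted p = 0.73 with an estimated correlation (called with rescaling, with the Y-linked covariate or after the length and GC correction, adjusted p = 0.020 to 0.033). Without isoproterenol 3 the gene count was 2779, and without the 4 libraries together it was 1940.

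With amiodarone, the immediate early list was higher and the mitosis list lower, both lost with an estimated correlation (adjusted p = 0.24 and 0.59). Nr4a1 (Entrez 15370), an immediate early nuclear receptor, rose (70.0 ± 18.8 against 7.67 ± 0.855 FPKM, log2 3.00 ± 0.43, adjusted p = 2.6e-04), as did the insulin receptor adaptor Irs2 (Entrez 384783; 20.2 ± 6.50 against 1.95 ± 0.309 FPKM, log2 2.80 ± 0.36, adjusted p = 1.1e-04) and the kinase Sik1, a target of cAMP signalling (log2 2.03 ± 0.23, adjusted p = 4.6e-05). Upk3b, a mesothelial membrane protein, rose (9.29 ± 1.07 against 1.77 ± 1.38 FPKM, log2 2.01 ± 0.49, adjusted p = 0.0070). Cxcr4 (Entrez 12767) fell (log2 -1.30 ± 0.14, adjusted p = 3.8e-05), and so did B2m (log2 -1.65 ± 0.50, adjusted p = 0.021, lost in several refits, adjusted p = 0.066 to 0.095). In all, 1053 genes were higher and 2555 lower (29.0% of those tested; 29.2% of calls higher, or 61.4% higher, 1784 against 1121, with rescaling). Of these, 27 higher and 26 lower genes changed by at least 1 log2. Unscaled, groups did not overlap in 5422 of 12433 genes.

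The immediate early list, genes switched on within minutes of a stimulus, was higher with amiodarone: 10 rose and 0 fell of 20 (11 and 0 over the list alone), median 0.45, including Egr1 (log2 1.24 ± 0.22, adjusted p = 0.0010). Camera gave immediate early genes adjusted p = 3.3e-09, and adjusted p = 0.24 with an estimated correlation. In the list of targets of the growth regulator YAP 7 rose and 0 fell of 17 (7 and 0 over the list alone), median 0.19, with Cyr61 rising (log2 0.66 ± 0.11, adjusted p = 8.3e-04). YAP targets were given adjusted p = 4.7e-05, and adjusted p = 0.26 with an estimated correlation. Of mitosis genes 0 rose and 14 fell of 33 (0 and 22 over the list alone), median -0.33, with Cks2 as an example (log2 -0.73 ± 0.12, adjusted p = 4.9e-04). With amiodarone the mitosis list had adjusted p = 7.7e-05, and adjusted p = 0.59 with an estimated correlation. Of DNA replication genes 0 rose and 9 fell of 30 (0 and 10 over the list alone), median -0.21. The DNA replication list had adjusted p = 0.028, and adjusted p = 0.69 with an estimated correlation (lost in several refits, adjusted p = 0.055 to 0.23).

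Of the adult sarcomere list under amiodarone 10 rose and 0 fell of 22 (11 and 0 over the list alone), median 0.14, including Myom1 (log2 0.50 ± 0.07, adjusted p = 1.6e-04). For the adult sarcomere list, adjusted p = 2.5e-04, and adjusted p = 0.27 with an estimated correlation. Of cardiac ion channels 9 rose and 3 fell of 25 (10 and 3 over the list alone), median 0.17. Camera gave cardiac ion channels adjusted p = 7.5e-05, and adjusted p = 0.26 with an estimated correlation. Of calcium handling genes 5 rose and 4 fell of 17 (5 and 4 over the list alone), median 0.05. The calcium handling list was given adjusted p = 0.043, and adjusted p = 0.26 with an estimated correlation (lost in several refits, adjusted p = 0.053 to 0.11). The sodium-calcium exchanger Slc8a1 rose (38.1 ± 8.36 against 15.6 ± 0.777 FPKM, log2 1.22 ± 0.16, adjusted p = 1.6e-04), and the calcium pump Atp2a2 rose (log2 0.71 ± 0.09, adjusted p = 1.2e-04). Of β-adrenergic pathway genes 11 rose and 3 fell of 21 (12 and 4 over the list alone), median 0.22, with Adcy5 rising (log2 0.74 ± 0.09, adjusted p = 1.1e-04). With amiodarone the β-adrenergic pathway list had adjusted p = 4.7e-05, and adjusted p = 0.17 with an estimated correlation. Fatty acid oxidation genes were higher as a list (12 rose and 0 fell of 28 (12 and 2 over the list alone), median 0.16). The fatty acid oxidation list had adjusted p = 2.1e-07, and adjusted p = 0.24 with an estimated correlation. Amiodarone's channel targets Kcnh2 and Hcn4 changed by 0.27 ± 0.08 for Kcnh2 and 0.69 ± 0.18 for Hcn4 (adjusted p at most 0.014; Kcnh2 lost without control 2, adjusted p = 0.088; Hcn4 lost in several refits, adjusted p = 0.054 to 0.12). Cacna1c did not pass (log2 0.03 ± 0.10, adjusted p = 0.83).

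Among other cell types under amiodarone, endothelial markers were lower as a list (0 rose and 8 fell of 18 (0 and 10 over the list alone), median -0.24), including Sox17 (log2 -0.51 ± 0.07, adjusted p = 1.5e-04). For endothelial markers, adjusted p = 0.010, and adjusted p = 0.48 with an estimated correlation. Of macrophage markers 0 rose and 5 fell of 18 (0 and 7 over the list alone), median -0.59. Camera gave macrophage markers adjusted p = 0.038, and adjusted p = 0.69 with an estimated correlation (lost in several refits, adjusted p = 0.054 to 0.22). Of neutrophil markers 4 rose and 1 fell of 10 (4 and 1 over the list alone), median 0.80, 0.36 without the 4 libraries. The granule gene Ltf rose (log2 0.94 ± 0.19, adjusted p = 0.0027), while S100a8 stood at 24.0 to 27.1 FPKM with amiodarone against 6.98, 54.5 and 9.05 FPKM in the controls. Neutrophil markers were given adjusted p = 0.020, and adjusted p = 0.57 with an estimated correlation (lost in several refits, adjusted p = 0.062 to 0.20). Of clock genes 4 rose and 0 fell of 17 (3 and 0 over the list alone), median 0.18, with Per1, which is also induced by cAMP (log2 1.18 ± 0.19, adjusted p = 5.6e-04). With amiodarone the circadian clock list had adjusted p = 0.0027, and adjusted p = 0.26 with an estimated correlation. The gene count was 2038 without amiodarone 2, 2114 without control 2 and 1123 without the 4 libraries.

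With metoprolol, the immediate early list was higher and the interferon response list lower, both lost with an estimated correlation (adjusted p = 0.20 and 0.64). Nr4a1 rose (74.3 ± 35.6 against 7.67 ± 0.855 FPKM, log2 3.02 ± 0.43, adjusted p = 1.8e-04), and so did Irs2 (log2 2.79 ± 0.36, adjusted p = 8.6e-05), Sik1 (45.8 ± 7.93 against 8.42 ± 0.412 FPKM, log2 2.30 ± 0.23, adjusted p = 1.3e-05) and Per1 (31.9 ± 1.98 against 9.74 ± 0.698 FPKM, log2 1.61 ± 0.19, adjusted p = 5.2e-05). The phosphatase Dusp1 rose (86.5 ± 5.39 against 42.7 ± 4.15 FPKM, log2 1.00 ± 0.09, adjusted p = 1.1e-05), and the G protein regulator Rgs2 (Entrez 19735) rose (22.3 ± 1.97 against 11.2 ± 0.785 FPKM, log2 0.94 ± 0.09, adjusted p = 1.3e-05). Among the largest falls were Tgtp2, an interferon-induced GTPase (log2 -2.12 ± 0.48, adjusted p = 0.0040), and the immunoproteasome subunit Psmb9 (log2 -1.53 ± 0.34, adjusted p = 0.0037). In all, 1179 genes were higher and 2731 lower (31.4% of those tested; 30.2% of calls higher, or 59.6% higher, 1911 against 1293, with rescaling). Of these, 23 higher and 35 lower genes changed by at least 1 log2. Unscaled, groups did not overlap in 5781 of 12433 genes.

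Immediate early genes were higher as a list with metoprolol (11 rose and 0 fell of 20 (12 and 0 over the list alone), median 0.55), as was the β-adrenergic pathway (12 rose and 4 fell of 21 (12 and 4 over the list alone), median 0.29), in which the phosphodiesterase Pde4b rose (log2 0.66 ± 0.08, adjusted p = 7.6e-05). Immediate early genes had adjusted p = 7.6e-10, and adjusted p = 0.20 with an estimated correlation. For the β-adrenergic pathway list, adjusted p = 4.9e-05, and adjusted p = 0.16 with an estimated correlation. Adrb1, a receptor that β-blockers bind, rose (log2 0.29 ± 0.09, adjusted p = 0.023, lost in several refits, adjusted p = 0.050 to 0.11). Of YAP targets 7 rose and 1 fell of 17 (9 and 1 over the list alone), median 0.21. Camera gave YAP targets adjusted p = 2.5e-04, and adjusted p = 0.36 with an estimated correlation.

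Of calcium handling genes 5 rose and 3 fell of 17 (6 and 5 over the list alone), median 0.09, -0.01 after the length and GC correction, with Atp2a2, Slc8a1 and the junctional protein Jph2 rising under metoprolol (0.80 ± 0.09 for Atp2a2, 1.04 ± 0.16 for Slc8a1 and 0.46 ± 0.06 for Jph2, adjusted p at most 3.9e-04). The calcium handling list was given adjusted p = 0.019, and adjusted p = 0.26 with an estimated correlation. Of cardiac ion channels 7 rose and 4 fell of 25 (9 and 4 over the list alone), median 0.15, with the inward rectifier Kcnj2 falling (log2 -0.51 ± 0.12, adjusted p = 0.0062). With metoprolol cardiac ion channels had adjusted p = 0.0054, and adjusted p = 0.44 with an estimated correlation. Of the adult sarcomere list 7 rose and 1 fell of 22 (7 and 1 over the list alone), median 0.05. The adult sarcomere list had adjusted p = 0.0038, and adjusted p = 0.44 with an estimated correlation. Of fatty acid oxidation genes 17 rose and 2 fell of 28 (17 and 2 over the list alone), median 0.18. For the fatty acid oxidation list, adjusted p = 3.5e-09, and adjusted p = 0.16 with an estimated correlation. Of mitosis genes 0 rose and 8 fell of 33 (0 and 5 over the list alone), median -0.24, with Cks2 falling (log2 -0.49 ± 0.12, adjusted p = 0.0056). Camera gave the mitosis list adjusted p = 0.023, and adjusted p = 0.72 with an estimated correlation (lost without control 2 or metoprolol 3, adjusted p = 0.084 to 0.22). Of DNA replication genes 0 rose and 16 fell of 30 (0 and 19 over the list alone), median -0.30. The DNA replication list was given adjusted p = 0.0028, and adjusted p = 0.64 with an estimated correlation.

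Of interferon response genes under metoprolol 0 rose and 10 fell of 18 (0 and 16 over the list alone), median -0.57, with Oas2 falling (log2 -0.58 ± 0.12, adjusted p = 0.0028). With metoprolol the interferon response list had adjusted p = 0.0020, and adjusted p = 0.64 with an estimated correlation. Of macrophage markers 0 rose and 9 fell of 18 (0 and 9 over the list alone), median -0.73, with C1qa falling (log2 -0.99 ± 0.21, adjusted p = 0.0029). Macrophage markers had adjusted p = 0.0086, and adjusted p = 0.64 with an estimated correlation (lost without control 2 or metoprolol 2, adjusted p = 0.053 to 0.11). The gene count was 2389 without metoprolol 1 and 2422 without control 2.

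With propranolol, the adult sarcomere list was higher and the interferon response list lower, both lost with an estimated correlation (adjusted p = 0.36 and 0.54). Ctgf (Entrez 14219), a matricellular protein and YAP target, rose (201 ± 39.2 against 54.8 ± 11.1 FPKM, log2 1.86 ± 0.23, adjusted p = 7.0e-05). Irs2 (8.13 ± 2.14 against 1.95 ± 0.309 FPKM, log2 1.61 ± 0.36, adjusted p = 0.0040), Per1 (log2 1.36 ± 0.19, adjusted p = 1.9e-04) and Sik1 (log2 1.22 ± 0.23, adjusted p = 0.0013) also rose. Cxcr4 fell (5.22 ± 0.997 against 15.9 ± 1.08 FPKM, log2 -1.45 ± 0.14, adjusted p = 8.6e-06), as did Tgtp2 (log2 -2.09 ± 0.48, adjusted p = 0.0048). In all, 868 genes were higher and 2464 lower (26.8% of those tested; 26.1% of calls higher, or 58.3% higher, 1672 against 1194, with rescaling). Of these, 17 higher and 44 lower genes changed by at least 1 log2. Unscaled, groups did not overlap in 5301 of 12433 genes.

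Among muscle genes under propranolol, Jph2 rose (171 ± 4.27 against 107 ± 5.15 FPKM, log2 0.68 ± 0.06, adjusted p = 6.8e-06), as did Atp2a2 (log2 0.69 ± 0.09, adjusted p = 1.1e-04). Of calcium handling genes 6 rose and 3 fell of 17 (6 and 3 over the list alone), median 0.08, -0.01 without the 4 libraries. For the calcium handling list, adjusted p = 0.012, and adjusted p = 0.36 with an estimated correlation. Of the adult sarcomere list 9 rose and 0 fell of 22 (9 and 0 over the list alone), median 0.10, with 0.64 ± 0.10 for Cmya5 and 0.33 ± 0.07 for Myh6 (adjusted p at most 0.0033). Camera gave the adult sarcomere list adjusted p = 1.5e-05, and adjusted p = 0.36 with an estimated correlation. Of cardiac ion channels 5 rose and 2 fell of 25 (6 and 2 over the list alone), median 0.12. Cardiac ion channels were given adjusted p = 0.0025, and adjusted p = 0.53 with an estimated correlation. Of the β-adrenergic pathway 7 rose and 4 fell of 21 (8 and 4 over the list alone), median 0.04, -0.01 without the 4 libraries, with Adcy5 rising (log2 0.77 ± 0.09, adjusted p = 6.2e-05), while Adrb1 did not pass (log2 0.02 ± 0.09, adjusted p = 0.91). With propranolol the β-adrenergic pathway list had adjusted p = 0.0085, and adjusted p = 0.36 with an estimated correlation. Of fatty acid oxidation genes 8 rose and 2 fell of 28 (10 and 2 over the list alone), median 0.12, with Pdk4, a kinase that restrains glucose oxidation, rising (log2 0.85 ± 0.18, adjusted p = 0.0027). The fatty acid oxidation list had adjusted p = 1.6e-05, and adjusted p = 0.36 with an estimated correlation. Of YAP targets, Ctgf among them, 5 rose and 0 fell of 17 (5 and 0 over the list alone), median 0.07. For YAP targets, adjusted p = 0.0020, and adjusted p = 0.54 with an estimated correlation. Of immediate early genes 4 rose and 0 fell of 20 (3 and 0 over the list alone), median 0.21. Camera gave immediate early genes adjusted p = 0.0018, and adjusted p = 0.54 with an estimated correlation. Mitosis genes did not pass as a list (0 rose and 7 fell of 33 (0 and 7 over the list alone), median -0.20), nor did DNA replication genes (0 rose and 5 fell of 30 (0 and 3 over the list alone), median -0.17). The mitosis list was given adjusted p = 0.072, and adjusted p = 0.68 with an estimated correlation (called with rescaling or without the 4 libraries, adjusted p = 0.0044 to 0.020). With propranolol the DNA replication list had adjusted p = 0.12, and adjusted p = 0.68 with an estimated correlation.

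Of interferon response genes under propranolol 0 rose and 13 fell of 18 (0 and 17 over the list alone), median -0.74, with Ifit3 falling (log2 -1.01 ± 0.19, adjusted p = 0.0015). The interferon response list had adjusted p = 1.5e-05, and adjusted p = 0.54 with an estimated correlation. Of macrophage markers 0 rose and 11 fell of 18 (0 and 14 over the list alone), median -0.86. For macrophage markers, adjusted p = 0.0020, and adjusted p = 0.54 with an estimated correlation. Of neutrophil markers 0 rose and 4 fell of 10 (0 and 6 over the list alone), median -0.73. Camera gave neutrophil markers adjusted p = 0.036, and adjusted p = 0.55 with an estimated correlation (lost in several refits, adjusted p = 0.062 to 0.32). Of endothelial markers 0 rose and 8 fell of 18 (0 and 8 over the list alone), median -0.22, with Sox18 falling (59.3 ± 2.00 against 102 ± 11.5 FPKM, log2 -0.77 ± 0.09, adjusted p = 6.2e-05). Endothelial markers were given adjusted p = 0.0078, and adjusted p = 0.54 with an estimated correlation. Of fibroblast markers 0 rose and 7 fell of 15 (0 and 7 over the list alone), median -0.26, with the transcription factor Tcf21 falling (log2 -0.45 ± 0.07, adjusted p = 2.4e-04). With propranolol fibroblast markers had adjusted p = 0.032, and adjusted p = 0.54 with an estimated correlation (lost in several refits, adjusted p = 0.055 to 0.17). Of lysosome genes 0 rose and 7 fell of 26 (0 and 9 over the list alone), median -0.22. The lysosome list had adjusted p = 0.032, and adjusted p = 0.56 with an estimated correlation (lost in several refits, adjusted p = 0.055 to 0.23). The gene count was 2012 without control 2, 2167 without propranolol 2 and 1361 without the 4 libraries.

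With lidocaine, Nr4a1 rose (129 ± 43.9 against 7.67 ± 0.855 FPKM, log2 3.85 ± 0.43, adjusted p = 9.8e-06), followed by Irs2 (27.6 ± 6.88 against 1.95 ± 0.309 FPKM, log2 3.25 ± 0.36, adjusted p = 9.1e-06), Sik1 (log2 2.80 ± 0.23, adjusted p = 5.2e-07), the nuclear receptor Nr4a3 (log2 2.77 ± 0.35, adjusted p = 3.0e-05) and Per1 (49.6 ± 10.1 against 9.74 ± 0.698 FPKM, log2 2.22 ± 0.19, adjusted p = 8.4e-07). Rgs2 rose (29.1 ± 4.27 against 11.2 ± 0.785 FPKM, log2 1.30 ± 0.09, adjusted p = 1.9e-07), and so did the cAMP phosphodiesterases Pde4b and Pde4d (0.91 ± 0.08 for Pde4b and 0.92 ± 0.08 for Pde4d, adjusted p at most 1.4e-06). Cxcr4 fell (3.95 ± 0.542 against 15.9 ± 1.08 FPKM, log2 -1.77 ± 0.14, adjusted p = 3.2e-07), and the fast skeletal muscle genes Tnnc2 and Mylpf fell (-3.10 ± 0.78 for Tnnc2 and -3.02 ± 0.73 for Mylpf, adjusted p at most 0.0056), beside their high values in control 3. In all, 1312 genes were higher and 3303 lower (37.1% of those tested; 28.4% of calls higher, or 56.4% higher, 2234 against 1729, with rescaling). Of these, 44 higher and 43 lower genes changed by at least 1 log2. Unscaled, groups did not overlap in 6030 of 12433 genes.

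Of immediate early genes under lidocaine 12 rose and 0 fell of 20 (12 and 0 over the list alone), median 0.43, including Dusp1 (log2 1.05 ± 0.09, adjusted p = 1.2e-06). For immediate early genes, adjusted p = 6.7e-09, and adjusted p = 0.21 with an estimated correlation. Of the β-adrenergic pathway 10 rose and 3 fell of 21 (10 and 3 over the list alone), median 0.21. Camera gave the β-adrenergic pathway list adjusted p = 7.0e-05, and adjusted p = 0.13 with an estimated correlation. Of YAP targets 6 rose and 1 fell of 17 (9 and 1 over the list alone), median 0.19. YAP targets were given adjusted p = 6.1e-04, and adjusted p = 0.41 with an estimated correlation. Of clock genes 4 rose and 1 fell of 17 (4 and 1 over the list alone), median 0.06, -0.04 after the length and GC correction. With lidocaine the circadian clock list had adjusted p = 0.032, and adjusted p = 0.41 with an estimated correlation (lost in several refits, adjusted p = 0.051 to 0.079). Of DNA replication genes 0 rose and 14 fell of 30 (0 and 16 over the list alone), median -0.25, with the histone mRNA binding protein Slbp falling (log2 -0.43 ± 0.07, adjusted p = 3.5e-04), and the mitosis list did not pass (0 rose and 2 fell of 33 (0 and 2 over the list alone), median -0.15). The DNA replication list had adjusted p = 0.037, and adjusted p = 0.72 with an estimated correlation (lost in several refits, adjusted p = 0.061 to 0.24). For the mitosis list, adjusted p = 0.42, and adjusted p = 0.91 with an estimated correlation.

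Among muscle genes under lidocaine, Jph2, Atp2a2 and Slc8a1 rose (0.69 ± 0.06 for Jph2, 0.82 ± 0.09 for Atp2a2 and 1.10 ± 0.16 for Slc8a1, adjusted p at most 1.2e-04). Of calcium handling genes 5 rose and 3 fell of 17 (5 and 4 over the list alone), median 0.07, -0.02 after the length and GC correction. Camera gave the calcium handling list adjusted p = 0.030, and adjusted p = 0.29 with an estimated correlation (lost in several refits, adjusted p = 0.054 to 0.064). Of cardiac ion channels 7 rose and 3 fell of 25 (7 and 3 over the list alone), median 0.07. Cardiac ion channels were given adjusted p = 0.0064, and adjusted p = 0.41 with an estimated correlation. Of the adult sarcomere list 9 rose and 1 fell of 22 (9 and 1 over the list alone), median 0.09. With lidocaine the adult sarcomere list had adjusted p = 0.0032, and adjusted p = 0.41 with an estimated correlation. Of fatty acid oxidation genes 17 rose and 1 fell of 28 (19 and 1 over the list alone), median 0.20, with the fatty acid sensor Ppara rising (log2 0.80 ± 0.12, adjusted p = 1.3e-04). The fatty acid oxidation list had adjusted p = 1.9e-09, and adjusted p = 0.13 with an estimated correlation.

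Of macrophage markers under lidocaine 0 rose and 10 fell of 18 (0 and 11 over the list alone), median -0.79, with Cx3cr1 falling (log2 -0.58 ± 0.10, adjusted p = 3.7e-04). For macrophage markers, adjusted p = 0.013, and adjusted p = 0.68 with an estimated correlation (lost without control 2 or lidocaine 2, adjusted p = 0.055 to 0.074). Of interferon response genes 0 rose and 12 fell of 18 (0 and 14 over the list alone), median -0.61, with Oas2 falling (log2 -0.73 ± 0.12, adjusted p = 3.5e-04). Camera gave the interferon response list adjusted p = 0.0034, and adjusted p = 0.60 with an estimated correlation.

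With ivabradine, Stbd1 (Entrez 52331) rose (21.9 ± 1.37 against 8.37 ± 2.03 FPKM, log2 1.31 ± 0.12, adjusted p = 2.0e-06), as did Tmem100, an endothelial membrane protein (29.6 ± 6.58 against 11.1 ± 0.651 FPKM, log2 1.32 ± 0.14, adjusted p = 8.6e-06). Ppargc1a (Entrez 19017), a coactivator of mitochondrial genes, rose (26.7 ± 7.83 against 10.9 ± 1.33 FPKM, log2 1.18 ± 0.16, adjusted p = 8.3e-05), and the lipoprotein lipase inhibitor Angptl4 (Entrez 57875) fell (34.2 ± 2.97 against 73.2 ± 6.79 FPKM, log2 -1.08 ± 0.14, adjusted p = 7.4e-05). Nr4a1 rose (64.5 ± 59.1 against 7.67 ± 0.855 FPKM, log2 2.56 ± 0.43, adjusted p = 4.7e-04), with library values of 31.3, 29.4 and 133 FPKM, and Sik1 and Per1 rose (2.11 ± 0.23 for Sik1 and 1.70 ± 0.19 for Per1, adjusted p at most 1.9e-05). In all, 984 genes were higher and 2374 lower (27.0% of those tested; 29.3% of calls higher, or 57.5% higher, 1739 against 1287, with rescaling). Of these, 29 higher and 44 lower genes changed by at least 1 log2. Unscaled, groups did not overlap in 4468 of 12433 genes.

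Of calcium handling genes under ivabradine 7 rose and 1 fell of 17 (7 and 2 over the list alone), median 0.09, with 0.64 ± 0.06 for Jph2 and 0.73 ± 0.09 for Atp2a2 (adjusted p at most 4.9e-05). The calcium handling list was given adjusted p = 0.0019, and adjusted p = 0.23 with an estimated correlation. Hcn4, the pacemaker channel that ivabradine blocks, did not pass (log2 0.39 ± 0.18, adjusted p = 0.12). Of cardiac ion channels 5 rose and 3 fell of 25 (7 and 4 over the list alone), median 0.13. With ivabradine cardiac ion channels had adjusted p = 0.0026, and adjusted p = 0.43 with an estimated correlation. Of the adult sarcomere list 8 rose and 0 fell of 22 (8 and 0 over the list alone), median 0.06. The adult sarcomere list had adjusted p = 3.6e-04, and adjusted p = 0.41 with an estimated correlation. Of the β-adrenergic pathway 9 rose and 5 fell of 21 (10 and 6 over the list alone), median 0.15, with 1.01 ± 0.09 for Rgs2 and 0.75 ± 0.08 for Pde4d (adjusted p at most 1.9e-05). For the β-adrenergic pathway list, adjusted p = 0.0019, and adjusted p = 0.23 with an estimated correlation. Of fatty acid oxidation genes 10 rose and 1 fell of 28 (10 and 1 over the list alone), median 0.12, including Ppara (log2 0.86 ± 0.12, adjusted p = 1.3e-04). Camera gave the fatty acid oxidation list adjusted p = 1.0e-05, and adjusted p = 0.24 with an estimated correlation. Of oxidative phosphorylation genes 6 rose and 1 fell of 37 (6 and 1 over the list alone), median 0.01, -0.03 without the 4 libraries, with Ndufs1 rising beside Ppargc1a (log2 0.40 ± 0.05, adjusted p = 8.0e-05). The oxidative phosphorylation list was given adjusted p = 0.015, and adjusted p = 0.67 with an estimated correlation (lost in several refits, adjusted p = 0.20 to 1.00).

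Of immediate early genes under ivabradine 5 rose and 0 fell of 20 (5 and 0 over the list alone), median 0.24, with 0.74 ± 0.08 for Klf4 and 0.88 ± 0.09 for Dusp1 (adjusted p at most 1.2e-05). With ivabradine immediate early genes had adjusted p = 2.8e-05, and adjusted p = 0.41 with an estimated correlation. Of clock genes 3 rose and 1 fell of 17 (3 and 1 over the list alone), median 0.04, -0.05 after the length and GC correction. The circadian clock list had adjusted p = 0.036, and adjusted p = 0.49 with an estimated correlation (lost in several refits, adjusted p = 0.050 to 0.11). Of mitosis genes 0 rose and 10 fell of 33 (0 and 10 over the list alone), median -0.26, with Cks2 falling (log2 -0.56 ± 0.12, adjusted p = 0.0023). For the mitosis list, adjusted p = 0.0055, and adjusted p = 0.64 with an estimated correlation (lost without ivabradine 1, adjusted p = 0.12). Of DNA replication genes 0 rose and 15 fell of 30 (0 and 21 over the list alone), median -0.31. Camera gave the DNA replication list adjusted p = 5.3e-04, and adjusted p = 0.55 with an estimated correlation.

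Of macrophage markers under ivabradine 0 rose and 9 fell of 18 (0 and 9 over the list alone), median -0.65, with Cx3cr1 falling (log2 -0.72 ± 0.10, adjusted p = 1.3e-04). Macrophage markers were given adjusted p = 0.0089, and adjusted p = 0.64 with an estimated correlation (lost without control 2, adjusted p = 0.070). Of interferon response genes 0 rose and 14 fell of 18 (0 and 17 over the list alone), median -0.66, with Ifit3 falling (log2 -0.86 ± 0.19, adjusted p = 0.0039). With ivabradine the interferon response list had adjusted p = 1.1e-04, and adjusted p = 0.50 with an estimated correlation. Of endothelial markers 0 rose and 9 fell of 18 (0 and 12 over the list alone), median -0.21, with Sox18 falling (log2 -0.49 ± 0.09, adjusted p = 0.0011). Endothelial markers had adjusted p = 0.011, and adjusted p = 0.50 with an estimated correlation. The gene count was 2216 without ivabradine 3, 2232 without the 4 libraries and 1560 in a fit of the 2 groups alone.

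**Figure D3:**
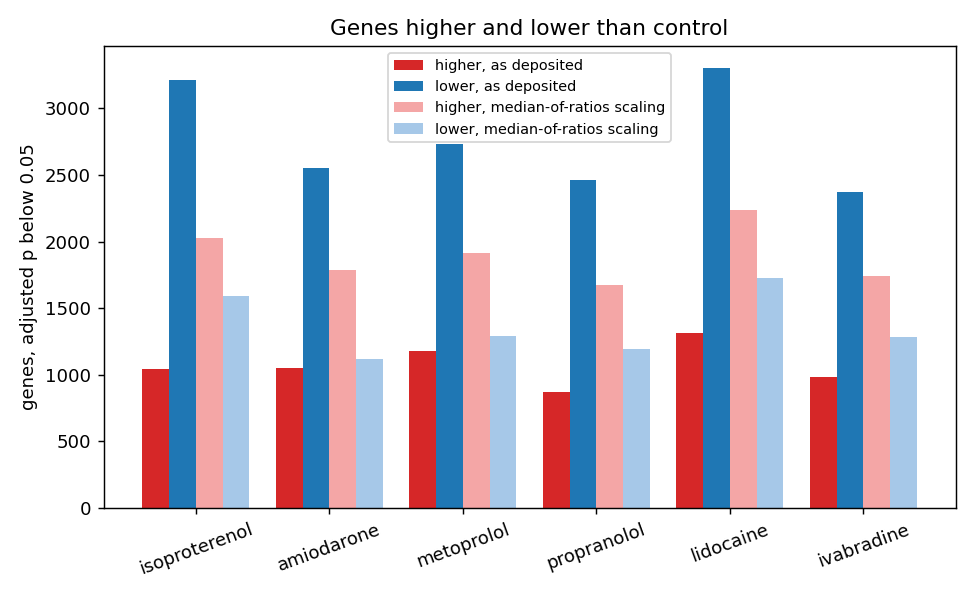
Number of genes called higher and lower for each drug against control (Benjamini-Hochberg adjusted p below 0.05, 12433 tested), without and with rescaling. The 6 comparisons hold 3332 to 4615 calls, or 2866 to 3963 with rescaling.

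The 6 drug groups differed from the controls largely in the same direction. In all 6 comparisons 347 genes were higher and 806 lower, out of 7455 called in any (746 and 252 of 6654 with rescaling), and 66 genes were called higher with 1 drug and lower with another. Irs2, Sik1 and Per1 rose in all 6, with mean log2 fold changes of 2.21, 1.90 and 1.45 (Irs2 with isoproterenol lost in several refits, adjusted p = 0.058 to 0.21), and Cxcr4, the immunoproteasome subunits Psmb9 and Psmb8 and the complement gene C1qa fell in all 6, with means of -1.37, -1.36, -1.07 and -0.98. Macrophage markers were called lower in 6 comparisons, interferon response genes in 5, and adult sarcomere, cardiac ion channel, β-adrenergic and fatty acid oxidation lists higher in 6. With an estimated correlation 0 of these calls held, except 1 of the 6 for fatty acid oxidation. The oxidative phosphorylation list, called with 2 drugs, was called with all 6 after the length and GC correction (adjusted p = 1.7e-18 to 0.011, medians -0.0004 to 0.19). Means per library separated drug from control for mitosis genes with isoproterenol, amiodarone, metoprolol, propranolol and ivabradine and for adult sarcomere genes with the first 4 of these (exact permutation p = 0.10), and not for the rest of these 2 lists (p = 0.20). None passed when adjusted over all 42 such tests (smallest adjusted p = 0.20). Fold changes correlated across genes at a mean r of 0.80 (0.66 to 0.91) between pairs of drugs, where genes are not independent replicates and simulated unchanged groups against the same controls gave 0.50. The mean covariance was 0.0581, against at most 0.00791 in 100 simulations in which each gene was drawn independently. Between drugs without isoproterenol, pairs shared 596 to 971 higher genes (68.7 to 124 for independent lists) and 1514 to 2250 lower genes (470 to 726), or 1200 to 1672 and 642 to 992 with rescaling.

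Cardiac growth regulators were called higher with amiodarone, metoprolol and lidocaine, with 5 to 6 members rising and 3 to 4 falling of 23 (5 to 6 and 4 over the list alone) and medians of 0.03 to 0.09. Their adjusted p = 0.020 to 0.038, and adjusted p = 0.35 to 0.47 with an estimated correlation, with the call lost in refits for each, and the median turned sign in a refit for lidocaine. Under metoprolol Gata6 rose and the cell cycle inhibitor Cdkn1c fell (0.51 ± 0.08 for Gata6 and -0.41 ± 0.09 for Cdkn1c), and under lidocaine Hand2 rose (log2 0.72 ± 0.09, adjusted p = 2.6e-05). Glucocorticoid responsive genes were called higher with metoprolol, lidocaine and ivabradine, with 5 members rising and 0 to 1 falling of 14 (5 and 0 to 2 over the list alone) and medians of -0.06 to 0.02, so median and test differed in sign in part. Their adjusted p = 0.0019 to 0.023, and adjusted p = 0.21 to 0.36 with an estimated correlation, with the call lost in refits for metoprolol, and the median turned sign in a refit for metoprolol and lidocaine. Thyroid hormone responsive genes were called higher with all 6 drugs, with 3 to 5 members rising and 1 to 3 falling of 17 (3 to 6 and 2 to 3 over the list alone) and medians of 0.01 to 0.14. Their adjusted p = 0.0069 to 0.045, and adjusted p = 0.19 to 0.53 with an estimated correlation, with the call lost in refits for each, and the median turned sign in a refit for metoprolol and propranolol. Klf9 rose with lidocaine (log2 0.60 ± 0.09, adjusted p = 9.9e-05). Epicardial and mesothelial markers were called higher with amiodarone, metoprolol, propranolol, lidocaine and ivabradine, with 0 to 6 members rising and 0 falling of 11 (0 to 6 and 0 to 2 over the list alone) and medians of 0.34 to 0.78. Their adjusted p = 1.9e-04 to 0.048, and adjusted p = 0.26 to 0.64 with an estimated correlation, with the call lost in refits for 3 of the 5 drugs. Skeletal muscle markers were called lower with metoprolol, lidocaine and ivabradine, with 0 members rising and 4 to 9 falling of 10 (0 and 8 to 9 over the list alone) and medians of -1.65 to -1.31. Their adjusted p = 0.010 to 0.036, and adjusted p = 0.55 to 0.64 with an estimated correlation, with the call lost in refits for each. Of this list Mylpf and Tnnc2 were highest in control 3. Cholesterol synthesis genes were called higher with propranolol, lidocaine and ivabradine, with 2 to 6 members rising and 1 to 3 falling of 22 (1 to 6 and 0 to 4 over the list alone) and medians of 0.02 to 0.04. Their adjusted p = 0.032 to 0.0498, and adjusted p = 0.50 to 0.54 with an estimated correlation, with the call lost in refits for each.

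Camera called no drug comparison with the control for 10 lists. These were fetal and stress sarcomere programme (17 tested, medians -0.11 to 0.17, smallest adjusted p = 0.12), glycolysis (20 tested, medians -0.03 to 0.04, smallest adjusted p = 0.054), extracellular matrix (30 tested, medians -0.35 to -0.20, smallest adjusted p = 0.10), smooth muscle and pericyte markers (12 tested, medians -0.07 to 0.06, smallest adjusted p = 0.054), erythroid markers (9 tested, medians -0.25 to 0.03, smallest adjusted p = 0.19), atrial markers (13 tested, medians -0.30 to 0.09, smallest adjusted p = 0.22), cytokines and chemokines (12 tested, medians -0.60 to -0.28, smallest adjusted p = 0.051), ER stress (18 tested, medians -0.32 to -0.02, smallest adjusted p = 0.14), heat shock (13 tested, medians -0.07 to 0.06, smallest adjusted p = 0.10) and hypoxia (15 tested, medians -0.24 to -0.07, smallest adjusted p = 0.077). At least 1 refit (rescaling, the Y-linked covariate, the length and GC correction, or the 4 libraries left out) called fetal and stress sarcomere programme with amiodarone and propranolol (0.020 to 0.042), glycolysis with isoproterenol, propranolol and lidocaine (0.019 to 0.046), extracellular matrix with isoproterenol (0.020 to 0.033), smooth muscle and pericyte markers with metoprolol and ivabradine (0.030 to 0.039), erythroid markers with isoproterenol (0.020), cytokines and chemokines with isoproterenol, propranolol and ivabradine (0.0034 to 0.0495) and heat shock with metoprolol (0.019) (adjusted p in brackets). Too few members were measured to test lymphocyte (4 of 13), adipocyte (4 of 12), and lung and liver markers (4 of 14), sex-linked genes (4) and mitochondrially encoded genes (0).

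**Figure D4:**
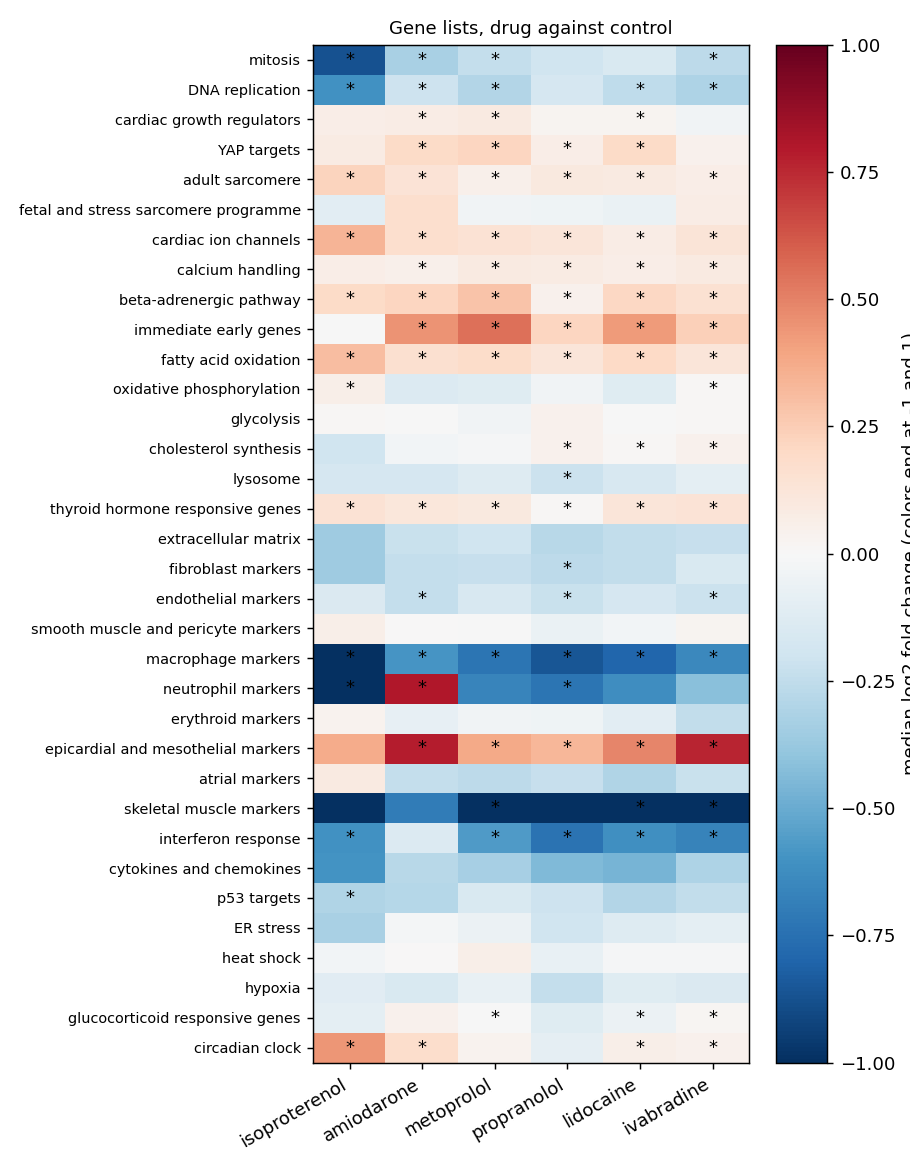
Median log2 fold change of each gene list for each of the 6 drugs against control, as a colour scale centred on 0. Macrophage marker medians lie between -1.26 and -0.59, and fatty acid oxidation medians between 0.12 and 0.31.

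**Figure D5:**
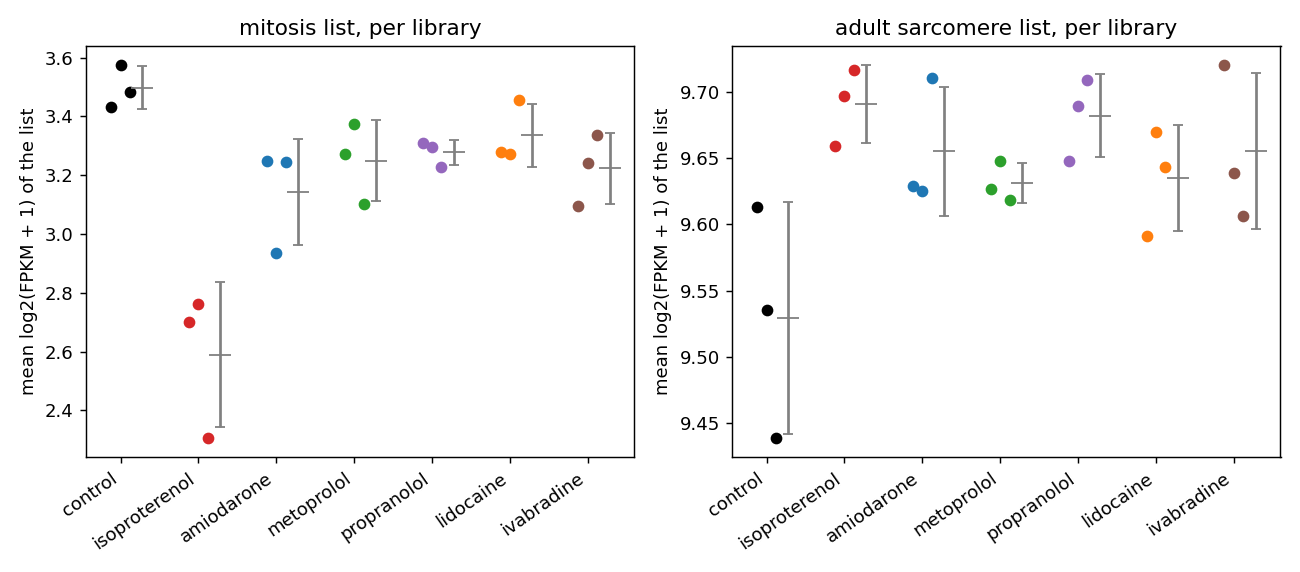
Mean log2(FPKM + 1) of gene lists in each of the 21 libraries, 1 point per library, by group. The mean of the 33 mitosis genes was 2.59 with isoproterenol and 3.50 in the controls.

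Metoprolol and propranolol are β-blockers that share an aryloxypropanolamine core with an N-isopropyl side chain, carrying a para-substituted phenyl ring in metoprolol and a naphthyl ring in propranolol. Doses are not in the labels, so the compounds cannot be compared at matched doses. Limma called 6 genes between them, 3 higher and 3 lower with metoprolol, with 1309 at an unadjusted p below 0.05. Higher with metoprolol were the small GTPase Rrad (log2 difference 0.75, 95% interval 0.49 to 1.01; 137 ± 32.1 against 80.4 ± 9.63 FPKM), the cardiac transcription factor Hand2 (0.59, 0.40 to 0.78) and Dusp1 (0.56, 0.36 to 0.76). Lower were Ttc27 (-0.47, -0.62 to -0.31) and Cpsf4 (-0.34, -0.46 to -0.22), all 5 at adjusted p = 0.032, and LOC108167571 (log2 difference -0.59, adjusted p = 0.038), which was named after its values were seen. Adrb1 (0.27, 0.08 to 0.46, adjusted p = 0.32) and Nr4a1 (2.03, 1.13 to 2.93, adjusted p = 0.098) did not pass. Intervals were -0.59 to 0.18 for Hcn4 and -0.004 to 0.41 for Cacna1c. In 12266 genes (98.7%) the interval lay within 1 log2 of 0, with a median distance of 0.17 from centre to bound. Each of the 5 calls with a full symbol was lost without 1 library or another (counts of 0 to 2), and the count was 0 without the 4 libraries. Camera called 11 lists here, of which 0 held with an estimated correlation and fry called 0.

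Isoproterenol, an agonist of the receptors that metoprolol and propranolol block, was compared with each. Its counts against amiodarone, lidocaine and ivabradine were 1035, 2031 and 2138. Against metoprolol 360 genes were higher and 643 lower (35.9% higher, or 47.8% higher, 463 against 505, with rescaling). Dbp was higher (log2 1.64 ± 0.15, adjusted p = 1.6e-05), as was the stress gene Gadd45a (log2 1.16 ± 0.12, adjusted p = 4.6e-05). Lower were Atf3, a stress-induced transcription factor, Irs2 and Cdkn1a (-1.94 ± 0.31 for Atf3, -1.82 ± 0.36 for Irs2 and -1.20 ± 0.10 for Cdkn1a, adjusted p at most 0.0047). Arntl, of the clock's positive arm, was lower (1.28 ± 0.803 against 4.54 ± 0.946 FPKM, log2 -1.32 ± 0.21, adjusted p = 0.0014), as were Ccnb1 and Rrm2 (-0.94 ± 0.12 for Ccnb1 and -0.96 ± 0.14 for Rrm2). Of mitosis genes 0 rose and 30 fell of 33 (0 and 32 over the list alone), median -0.68. For the mitosis list, adjusted p = 7.8e-28, and adjusted p = 0.20 with an estimated correlation. Adrb1 did not differ detectably (log2 -0.02 ± 0.09, adjusted p = 0.91; 0.003 with rescaling). Without isoproterenol 3, metoprolol 1, metoprolol 2 or metoprolol 3 the count was 418, 650, 594 or 413, it was 493 in a fit of the 2 groups alone, and 307 without the 4 libraries.

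Against propranolol, isoproterenol gave 808 higher and 1013 lower genes (44.4% higher, or 50.2% with rescaling, 917 against 908). Higher were Dbp (log2 1.77 ± 0.15, adjusted p = 9.1e-06) and the clock repressor Nr1d1 (log2 0.99 ± 0.15, adjusted p = 3.8e-04). Lower were Ctgf (log2 -2.00 ± 0.23, adjusted p = 6.5e-05), the natriuretic peptide Nppb (127 ± 8.40 against 503 ± 159 FPKM, log2 -1.92 ± 0.33, adjusted p = 0.0010) and the mitosis genes Aurka and Top2a (-0.97 ± 0.14 for Aurka and -0.96 ± 0.14 for Top2a, adjusted p at most 3.3e-04). Of mitosis genes 0 rose and 32 fell of 33 (0 and 32 over the list alone), median -0.75. Camera gave the mitosis list adjusted p = 1.9e-25, and adjusted p = 0.23 with an estimated correlation. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were lower (-4.14 ± 1.35 for Eif2s3y, -3.10 ± 1.02 for Ddx3y and -2.03 ± 0.65 for Kdm5d; each lost in refits, for Eif2s3y at adjusted p = 0.052 to 0.87), beside 0 isoproterenol and 3 propranolol libraries with Y-linked transcripts. The count was 1111 without isoproterenol 3, 957 without propranolol 2, 1152 without propranolol 3, 691 with a Y-linked covariate and 882 without the 4 libraries.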

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

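The tests listed above as chosen after the data were examined were chosen after the results were seen, and the other alternatives were fixed before. Across counts, covariance and list means, 504 values stayed the same by direction or a 1.5-fold bound, and 94 moved. Of named calls against control, 11 of 76 (isoproterenol) to 27 of 85 (amiodarone) were lost without 1 library. Where no cause is given, the cause was not tested. Count-based tools were not run, because the table holds no counts.

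With correlation estimated per list, the called lists numbered 2 for isoproterenol and 0 for amiodarone, metoprolol, propranolol, lidocaine, ivabradine and isoproterenol against the other 5 drugs. With no filter on low values, metoprolol against propranolol gave 0 genes and the 5 anti-arrhythmic drugs 76. With the Y-linked covariate these counts were 1 for metoprolol against propranolol, 691 for isoproterenol against propranolol and 1701 for isoproterenol against the other 5 drugs. Without the 4 libraries, which leaves fewer samples, counts were 1940 (isoproterenol), 1123 (amiodarone), 1361 (propranolol), 2232 (ivabradine), 0 (metoprolol against propranolol), 307 (isoproterenol against metoprolol), 882 (isoproterenol against propranolol), 1384 (isoproterenol against the other 5), 2153 (7 groups) and 11 (5 anti-arrhythmic drugs). In fits of the compared groups alone, with fewer residual degrees of freedom, they were 1560 (ivabradine), 3 (metoprolol against propranolol) and 493 (isoproterenol against metoprolol). The covariance shared between drugs was 0.0945 with a pseudocount of 0.1, 0.0422 with no filter and 0.0499 after the length and GC correction.

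Leaving out each library in turn gave 2779 to 4173 genes for isoproterenol against control, 2038 to 3432 for amiodarone, 2389 to 3682 for metoprolol, 2012 to 3236 for propranolol, 3247 to 4393 for lidocaine and 2216 to 3826 for ivabradine. It gave 0 to 2 for metoprolol against propranolol, 413 to 853 for isoproterenol against metoprolol, 957 to 1562 for isoproterenol against propranolol, 3417 to 5380 among the 7 groups and 70 to 134 among the 5 anti-arrhythmic drugs. For isoproterenol against the other 5 it gave 1596 to 3237. Called lists numbered 14 to 19, 11 to 18, 13 to 18, 12 to 20, 12 to 20 and 15 to 20 for isoproterenol, amiodarone, metoprolol, propranolol, lidocaine and ivabradine, and 11 to 15 for isoproterenol against the other 5. The mean of mitosis genes per library differed from control by -0.99 to -0.77 (isoproterenol), -0.41 to -0.25 (amiodarone), -0.31 to -0.17 (metoprolol), -0.25 to -0.18 (propranolol), -0.22 to -0.12 (lidocaine) and -0.33 to -0.21 (ivabradine).

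Some log2 values turned sign. Cacna1c stood at -0.11 (amiodarone), -0.079 (metoprolol), -0.11 (lidocaine) and -0.033 (ivabradine) after the length and GC correction, and at -0.024 (amiodarone) without the 4 libraries. Adrb1 stood at 0.0026 with rescaling and 0.024 without the 4 libraries for isoproterenol against metoprolol, and at -0.026 for propranolol without them. Without those libraries Myl4 stood at -0.015 for isoproterenol against the other 5 (0.95 with all libraries), since isoproterenol 3 held its atrial signal. With the Y-linked covariate Eif2s3y and Ddx3y, called without it for isoproterenol against propranolol, stood at 0.047 and 0.071 (-4.14 and -3.10 without it), by construction of the covariate. Leaving out single libraries moved Cacna1c from -0.016 to 0.088 (amiodarone), from -0.024 to 0.080 (lidocaine) and from -0.062 to 0.090 (ivabradine), and Adrb1 from -0.029 to 0.050 (propranolol), from -0.063 to 0.074 (ivabradine) and from -0.088 to 0.063 (isoproterenol against metoprolol). It moved Myl4 from -0.020 to 1.52 (isoproterenol against the other 5) and Hcn4 from -0.40 to 0.0064 (metoprolol against propranolol).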

Other observations

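Each drug against the other 5 drugs, the splits of the libraries and the tests of explanations were chosen after the results were seen, except the test with macrophage markers as a covariate, whose prediction was written before its value was known.

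Against the other 5 drug groups, a contrast with no control library, isoproterenol gave 1182 higher and 1649 lower genes (1445 and 1458 with rescaling), or 1596 in all without isoproterenol 3. Dbp was higher (log2 1.47 ± 0.12, adjusted p = 6.9e-07), as were the clock genes Tef and Per3 (0.77 ± 0.07 for Tef and 0.84 ± 0.09 for Per3), and Arntl was lower (log2 -1.01 ± 0.17, adjusted p = 3.5e-04). The natriuretic peptide Nppb and the cytokine receptor Tnfrsf12a were lower (-1.47 ± 0.26 for Nppb and -1.29 ± 0.17 for Tnfrsf12a). For the other drugs the counts were 10 for amiodarone, 0 for metoprolol (631 at an unadjusted p below 0.05 in limma), 81 for propranolol, 110 for lidocaine and 141 for ivabradine. Without 1 library these ran from 0 (amiodarone 1 or 3 left out) to 29 (lidocaine 3) for amiodarone, 0 for metoprolol, 7 (propranolol 2 or 3) to 103 (isoproterenol 2) for propranolol, 13 (lidocaine 2) to 179 (ivabradine 3) for lidocaine and 6 (ivabradine 3) to 218 (ivabradine 2) for ivabradine. For amiodarone the count was 4 with a filter at 5 FPKM, 5 with the title number as a block, 32 after the length and GC correction, 26 in a fit of the compared groups alone and 0 without the 4 libraries left out for other-tissue markers. For propranolol it was 22 with no filter, 14 with the Y-linked covariate, 130 after the length and GC correction and 8 without the 4 libraries, for lidocaine 55 with no filter and 35 without the 4 libraries, and for ivabradine 67 with no filter, 93 with the Y-linked covariate and 52 without the 4 libraries. Ctgf was higher with propranolol (log2 1.37 ± 0.18, adjusted p = 0.0014), and Pde4b with lidocaine (log2 0.46 ± 0.06, adjusted p = 0.0020).

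Among the 10 splits of the 6 libraries of a comparison, too few for a share under 0.05, the real split alone (1 of 10) reached its count of genes in each comparison. Real and highest other counts were 4254 and 9 for isoproterenol against control, 3608 and 0 for amiodarone, 3910 and 335 for metoprolol, 3332 and 0 for propranolol, 4615 and 224 for lidocaine, 3358 and 0 for ivabradine, 6 and 1 for metoprolol against propranolol, 1003 and 0 for isoproterenol against metoprolol, and 1821 and 0 for isoproterenol against propranolol. Called lists were as many in 8 of 10 splits for isoproterenol (13, highest other 22), 2 for amiodarone (16, 16), 3 for metoprolol (16, 19), 3 for propranolol (16, 18), 5 for lidocaine (17, 19) and 1 for ivabradine (18, 16), again too few splits for a share under 0.05.

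In 100 splits of 18 drug libraries, 1 reached the isoproterenol count (2831, highest other 540) and 3 the ivabradine count (141, highest other 510). Both shares, under 0.05, are unadjusted for the 6 drugs, in contrasts chosen after the results were seen. The ivabradine count was 6 without ivabradine 3. Chance was not excluded for amiodarone (5 of 100 splits, 10 against 745), metoprolol (100, 0 against 92), propranolol (6, 81 against 2831), lidocaine (5, 110 against 697) or the isoproterenol lists (23, 12 against 20). The splits with 2831, 745, 697 and 510 genes set apart 3, 2, 2 and 2 isoproterenol libraries, which points to a structure of the samples, but splits with 567 and 540 genes set apart 0. Among 100 random groupings 1 reached the real count for the 7 groups (4962, highest other 30) and 1 for the 5 anti-arrhythmic drugs (132, highest other 9), so chance was excluded there, though the 132 fell to 11 without the 4 libraries and to 76 with no filter.

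All 6 drug groups differed from the control largely in the same direction. The shared controls alone were excluded as the cause only if genes vary independently, as simulated (mean covariance 0.0581, highest simulated 0.00791). Length and GC explained 11.5% of mean fold change variance (Spearman rho with length 0.36). They were not the whole cause: 1269 genes were called alike in all 6 comparisons after correction. Separate handling or sequencing of the controls (no batch label) cannot be told apart from a drug effect on the 1153 shared genes. The controls stood apart in relative depth, genes of at least 1 FPKM and rescaling factor (1.05 to 1.07, drugs 0.966 to 1.01). They did not in summed FPKM or genes above 0.

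Proliferation genes (63) were lower with isoproterenol than with the other 5 drugs, at a median log2 difference of -0.51 with 54 called. As lists, mitosis and DNA replication did not pass with an estimated correlation (adjusted p = 0.21 for both), and 23 of 100 splits called as many lists. Sex was excluded as the whole cause (-0.50 with the Y-linked covariate), as were atrial RNA in isoproterenol 3 (-0.43 without it) and fewer macrophages (-0.56 with macrophage markers as a covariate). A β-agonist effect on proliferation may underlie the difference, a hypothesis that no value here tests.

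Dbp, Tef and Per3 were higher with isoproterenol than with the other 5 drugs. Another time of day at collection is a candidate explanation, since Arntl, which cycles in antiphase, was lower (-1.01). Induction of Per1 by the agonist cannot be told apart from it. Per1 was lower than with the other 5 drugs (-0.996). Against control Per1 was higher in all 6 groups (0.62 with isoproterenol), which may lie in drugs or controls. Sex was excluded, since Dbp stood at 1.42 with the Y-linked covariate. Collection times are not in the labels.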
